A study of Saccharomyces cerevisiae with 24 samples.

How the data were processed

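The series holds 24 two-colour arrays of Saccharomyces cerevisiae. Per the labels, Cy5 carried total RNA of the strain and Cy3 carried yeast genomic DNA. The strains are SS330, taken as the comparison strain, prp17 null, prp17-1 and prp22-1, each sampled at 23C (0 min) and after 5, 15, 30, 60 and 120 min at 37C, with 1 array per strain and time.

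The values are log2 ratios as deposited by the authors, and no other intensity was used. The base of the logarithm is not stated in the labels and was taken as 2. Background correction, normalization and spot filtering are not given in the sources used here. The values of an array centre near 0, and the values at time 0 vary too little between probes (SD 0.362 to 0.519) for a plain ratio of RNA to genomic DNA, so each probe's baseline is unknown. It cancels in differences between arrays, and no level is compared between probes. The direction (RNA over DNA) was read from the values, from CDC40 being low in prp17 null and heat shock genes being high at 37C.

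The median over probes, in the order of the 6 times, was 0.01, 0.01, 0.01, -0.01, -0.02 and -0.01 in SS330, -0.00, 0.04, 0.00, 0.06, 0.04 and 0.12 in prp17 null, -0.03, -0.03, 0.03, 0.02, 0.02 and 0.03 in prp17-1 and -0.02, -0.00, -0.01, 0.07, -0.01 and 0.00 in prp22-1. The share of probes with a value was 95.2%, 96.2%, 92.7%, 98.0%, 97.4% and 97.3% in SS330, 83.5%, 81.5%, 90.4%, 79.8%, 91.6% and 85.8% in prp17 null, 96.8%, 95.1%, 97.4%, 93.8%, 96.0% and 94.1% in prp17-1 and 98.1%, 98.1%, 77.3%, 98.4%, 97.8% and 97.5% in prp22-1. The values do not hold signal over background, so depth cannot be given in that unit. All pairs of arrays correlated positively (lowest r 0.306). For the main fits each array was centred on its median.

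Of 6350 probes, 5527 carry the name of 1 of 5493 genes and 823 have none, of which 237 lie after the last named probe. The 33 genes with several probes were tested probe by probe. A probe was tested when it had a value on at least 20 of the 24 arrays and on at least 3 of the 5 arrays at 37C of each strain, which left 5487, 4871 of them named, and left out 863. A value was present on all arrays for 2516.

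Linear models were fitted with limma 3.58.1 in R 4.3.3, with moderated t-tests and the Benjamini-Hochberg adjustment over all tested probes, and a probe was called at an adjusted p under 0.05. The comparisons of strains at 37C and the interactions of strain and temperature used the time point as a block, and the temperature shift used the strain as a block and the time as a factor. The interaction was tested where time 0 had a value. A fit with no block was made as a check. Gene lists, 32 in all, were tested with camera at its preset correlation of 0.01, repeated with an estimated correlation, and with fry on probes complete over all arrays. In the results fry is quoted only for the interrupted-frame list and the unnamed probes. Some lists that did not pass with an estimated correlation passed in fry, such as heat shock in the shift (fry adjusted p = 0.000217) and in prp17 null (0.00964). Others passed in neither, such as ribosomal protein genes with an interrupted frame in prp17 null (fry adjusted p = 0.101). Counts of list members are given over all genes and, where said, adjusted over the list alone. Tables and figures were made in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. The fits were tested on simulated data with known changes.

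Genes were named by a rule. A named gene had an adjusted p under 0.05 and the same sign at all 5 times (for the shift, in all 4 strains). The 8 largest rises and 8 largest falls were named, and 2 members of each list with a camera adjusted p under 0.05. CDC40, PRP22 and the mating and marker genes were always named, and for a comparison with no passing gene those with the smallest p. The comparisons, the lists except those of reading frames, textbook introns and unnamed probes, the filter, the naming rule and most alternatives were chosen before the data were examined.

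No intron annotation was given, so the planned comparison of introns with their exons was not run. In its place a list of genes with an interrupted frame was made, defined by a length from start to stop codon that is not a multiple of 3 and is under 5000, with 159 probes, 56 of them of ribosomal protein genes. Of 6021 protein-coding genes 96.3% have a length that is a multiple of 3. The list misses introns whose length keeps the frame, such as that of ACT1, and RPL22B falls outside it though it is known to have an intron. It takes in genes with a programmed frameshift, such as EST3, ABP140 and OAZ1.

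The alternatives tried were values as deposited without centring, centring without ribosomal protein genes, quantile normalization, filters at 12 arrays and at all arrays, an adjusted p under 0.01, trend and robust settings, no block, only the arrays of the strains compared, only the early or the late times, and leaving out each array in turn. Array weights and leaving out the 4 arrays with a value for under 85% of the probes were added after the data were seen.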

Results

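The series followed Saccharomyces cerevisiae through a shift from 23C to 37C on 24 arrays. It compared the strain SS330 with 3 strains mutant for pre-mRNA splicing factors, named in the labels as prp17 null, prp17-1 and prp22-1. PRP17, listed today as CDC40, encodes a protein of the spliceosome that acts around the second catalytic step, and PRP22 encodes the RNA helicase that releases the spliced mRNA. Each strain was sampled at 6 time points, at 0 min before the shift and at 5, 15, 30, 60 and 120 min after it, with 1 array per strain and time. Of 6350 probes, an array held a value for 77.3% to 98.4%. The lowest shares were on the prp22-1 array at 15 min (77.3%) and the prp17 null arrays at 30 min (79.8%), 5 min (81.5%) and 0 min (83.5%). The number of arrays limits the precision. In the strain comparisons the spread behind each p-value is that between time points of 1 course per strain, after a time effect shared by the strains. It was estimated from all 24 arrays together, so the strains not compared also set it. Time points of a course are not independent cultures, so a strain cannot be told apart from its culture. For the temperature shift the spread is that between the 4 strains, 3 of them mutant, in their change over time. A gene named below for a strain comparison passed at an adjusted p under 0.05 and had the same sign at all 5 times at 37C, unless its value is given as not passing. For the temperature shift the mean change had the same sign in all 4 strains. CDC40, PRP22, STE2 and the marker genes HIS3, LEU2, LYS2, TRP1 and URA3 are given for the shift and for the strains at 37C whatever their signs. Genes named only to list the members of a small count were chosen after their values were seen, and some of them lack a value at some times.

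CDC40 itself was low in the prp17 null strain. Its mean log2 ratio at 37C was -1.48 ± 0.51 (SD, n = 5) there and 0.10 ± 0.25 (SD, n = 5) in SS330, a difference of -1.58 ± 0.16 (SE, adjusted p = 1.35e-05). The difference was already -2.22 at time 0. In prp17-1 the mean was 0.23 ± 0.33 (SD, n = 5) and in prp22-1 -0.16 ± 0.22 (SD, n = 5), and neither difference from SS330 passed (0.13, adjusted p = 0.701, and -0.26, adjusted p = 0.431). The PRP22 signal did not pass in prp22-1 (0.09 ± 0.17 SE, adjusted p = 0.839) but was higher in the prp17 null strain (0.76 ± 0.17 SE, adjusted p = 0.00327). A point mutation need not change the level of its mRNA, so for prp17-1 and prp22-1 these values do not check the labels. The low CDC40 value in prp17 null was itself used, with the heat shock genes, to read the direction of the ratio. It is therefore not an independent check of that label. HIS3, a histidine biosynthesis gene widely used as a selection marker, was 2.37 ± 0.15 (SE, adjusted p = 8.5e-08) higher in the prp17 null strain, and 2.53 higher at time 0. At time 0 its value was 0.31 there, against -2.22 in SS330, -1.58 in prp17-1 and -1.86 in prp22-1. The genotypes of the strains at HIS3 are not known here, so a difference in strain background is not excluded.

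**Figure D1:**
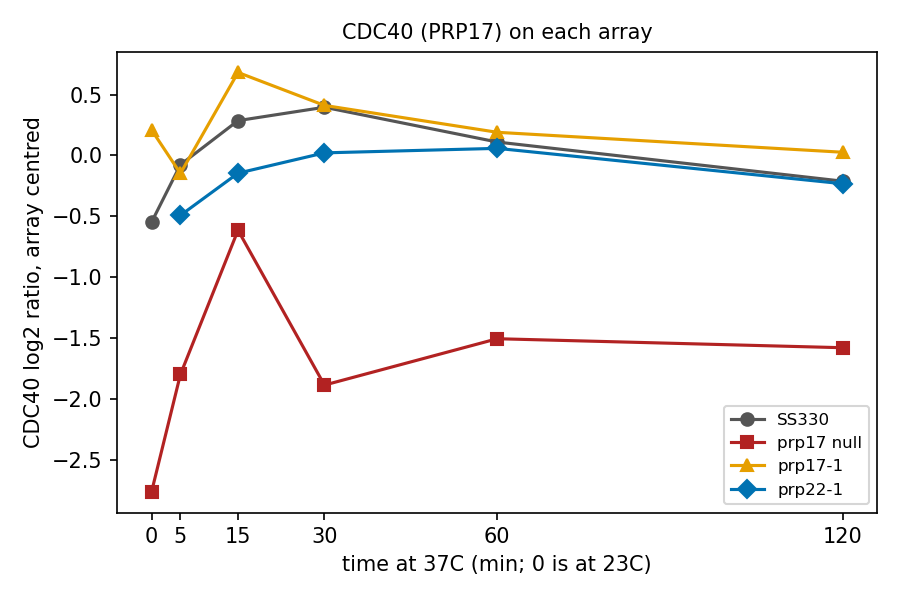
CDC40 (PRP17) on each array, as the centred log2 ratio (vertical axis) against minutes at 37C (horizontal axis, 0 is at 23C), with 1 point per array and 1 line per strain and no error bars. The prp17 null points lie between -2.76 and -0.62 and below those of the other strains at every time, and prp22-1 has no value at time 0.

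The temperature shift raised genes of the heat and general stress responses and lowered genes that make ribosomes, histones and cell cycle regulators. With an estimated correlation none of these lists passed. The adjusted p was 0.0551 for heat shock and for general stress, and 0.173 to 0.405 for the others. Among genes with the same sign in all strains the largest rises were in SPI1, which encodes a cell wall protein (4.16 ± 0.46 on the log2 scale, SE, adjusted p = 2.47e-05), and SSA3, an Hsp70 chaperone gene (3.39 ± 0.53, adjusted p = 0.000192). SOL4 of the pentose phosphate pathway rose by 3.26, TFS1, an inhibitor of carboxypeptidase Y, by 3.17, the chaperone gene SSE2 by 2.84, HSP12 by 2.66, the glutamate decarboxylase gene GAD1 by 2.60 and the catalase gene CTT1 by 2.60. The largest falls among them were in ribosomal protein genes, with RPS8A at -1.85 ± 0.41 (SE, adjusted p = 0.00236), RPS29A at -1.84, RPL20A at -1.83, RPL24A at -1.80 and RPS3 at -1.79. RPS8B (-1.72), RPS25A (-1.69) and RPS26B (-1.69) fell too. CDC40 passed (0.65, adjusted p = 0.0146), with 0.65 in SS330 and 1.29 in prp17 null. It was 0.02 in prp17-1 and had no value in prp22-1, so it did not meet the rule on signs. The largest rise was in the strain null for this gene, with values between -2.76 and -0.62. What the probe measured there is not known, so the call alone does not show that CDC40 mRNA rose. LYS2 fell by 0.60 on the log2 scale (adjusted p = 0.0333). PRP22 (0.14), STE2 (-0.59), HIS3 (-0.16), LEU2 (-0.11), TRP1 (0.03) and URA3 (-0.20) did not pass.

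Of 27 heat shock and chaperone genes, 25 rose and 1, the mitochondrial cochaperone gene MGE1, fell (-0.80), and adjusted over the list alone the counts were 25 and 1. Of 33 trehalose, glycogen and general stress genes 28 rose, 30 adjusted over the list alone. With an estimated correlation the adjusted p was 0.0551 for each of these lists. Of 20 cell wall integrity genes 11 rose (13 higher and 2 lower adjusted over the list alone), with PST1 at 1.43 and CWP1 at 1.32, both cell wall mannoproteins (adjusted p = 0.0683 with an estimated correlation). Of 33 proteasome genes, RPN11 (0.66), PRE7 (0.44), PRE6 (0.44) and UFD1 (0.41) rose, which are 4, against 0 adjusted over the list alone. The list's median of 0.21 turned to -0.09 under quantile normalization (adjusted p = 0.682 with an estimated correlation), and PRE7 reversed there too. Of 43 respiratory chain and citric acid cycle genes 16 rose and 1, NDI1, fell, the same counts adjusted over the list alone, with the citrate synthase gene CIT1 at 1.84 and the isocitrate dehydrogenase gene IDH2 also higher. Their median of 0.25 turned to -0.01 under quantile normalization (adjusted p = 0.522 with an estimated correlation).

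Ribosomal protein genes fell almost as a body. Of 73 whose frame from start to stop codon was not interrupted, 71 fell (72 adjusted over the list alone, median -1.23), and of 53 with an interrupted frame 48 fell (51 adjusted over the list alone, median -1.03), among them RPS4B at -1.65 and RPL13A at -1.59. With an estimated correlation the adjusted p was 0.229 and 0.281. All 32 measured ribosomal protein genes known from textbooks to lack an intron, a list chosen after the data were seen, fell (32 adjusted over the list alone, adjusted p = 0.236 with an estimated correlation). Of 64 ribosome biogenesis genes 48 fell and 1, ERB1, rose (55 and 1 adjusted over the list alone), with the small nucleolar ribonucleoprotein gene NOP56 at -1.33 and the large subunit assembly gene BRX1 at -1.26. Of 20 RNA polymerase I and III genes 9 fell (11 adjusted over the list alone), with the polymerase I genes RPA43 and RPA49 at -0.92 each. With an estimated correlation these lists had an adjusted p of 0.173 and 0.236. Of 28 translation factor genes 20 fell (21 adjusted over the list alone), with the elongation factor genes YEF3 at -1.23 and EFT2 at -1.19 (adjusted p = 0.0683 with an estimated correlation).

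All 10 histone genes fell (10 adjusted over the list alone), HTA1 by 1.48 and HTB1 by 1.37 on the log2 scale. Of 29 G1/S genes 17 fell (18 adjusted over the list alone), with the G1 cyclin gene CLN2 at -1.11 and SVS1 at -1.23. Of 20 G2/M genes 9 fell and 1, YNL058C, rose (10 and 1 adjusted over the list alone), with the mitotic cyclin gene CLB2 at -1.03 and the transcription factor gene SWI5 at -0.88. For histones, G1/S and G2/M the adjusted p was 0.236, 0.229 and 0.405 with an estimated correlation. Of 51 amino acid biosynthesis genes 21 fell (24 lower and 3 higher adjusted over the list alone), with ILV3 of the branched-chain pathway at -1.43 and ARO4 of the aromatic pathway at -1.29 (adjusted p = 0.217 with an estimated correlation). Of 34 RNA export and decay genes 14 fell (18 adjusted over the list alone), with the mRNA export genes YRA1 at -1.15 and SUB2 at -1.02. This list alone among those named for the shift kept its call with an estimated correlation (adjusted p = 0.00389), which was 0.02 from 16 complete genes. In SS330 its median relative to time 0 was -0.304 at 5 min and 0.003 at 120 min. At 120 min it was -0.377 in prp17 null, -0.234 in prp17-1 and -0.409 in prp22-1, so the fall at that time came from the mutants. Of its genes 3 have an interrupted frame, YRA1 among them. Of 86 other genes with an interrupted frame 30 fell and 2, PAL2 and NCE101, rose, the same counts adjusted over the list alone, with the RNA polymerase subunit gene RPO26 at -1.18 and the alpha-tubulin gene TUB1 at -1.17 (adjusted p = 0.354 with an estimated correlation). In SS330 this list's median stayed between -0.06 and 0.01 relative to time 0. At 60 min it was -0.68 in prp17 null, -0.40 in prp17-1 and -0.48 in prp22-1, so the list's fall came from the mutants.

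In all, 1690 of 5487 tested probes changed with the shift, 766 higher and 924 lower (limma, adjusted p under 0.05). Against time 0, 1348 probes changed at 5 min, 1665 at 15 min, 982 at 30 min, 357 at 60 min and 996 at 120 min. Without the strain as a block the count was 1063, and without the prp17-1 arrays it was 906.

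**Figure D2:**
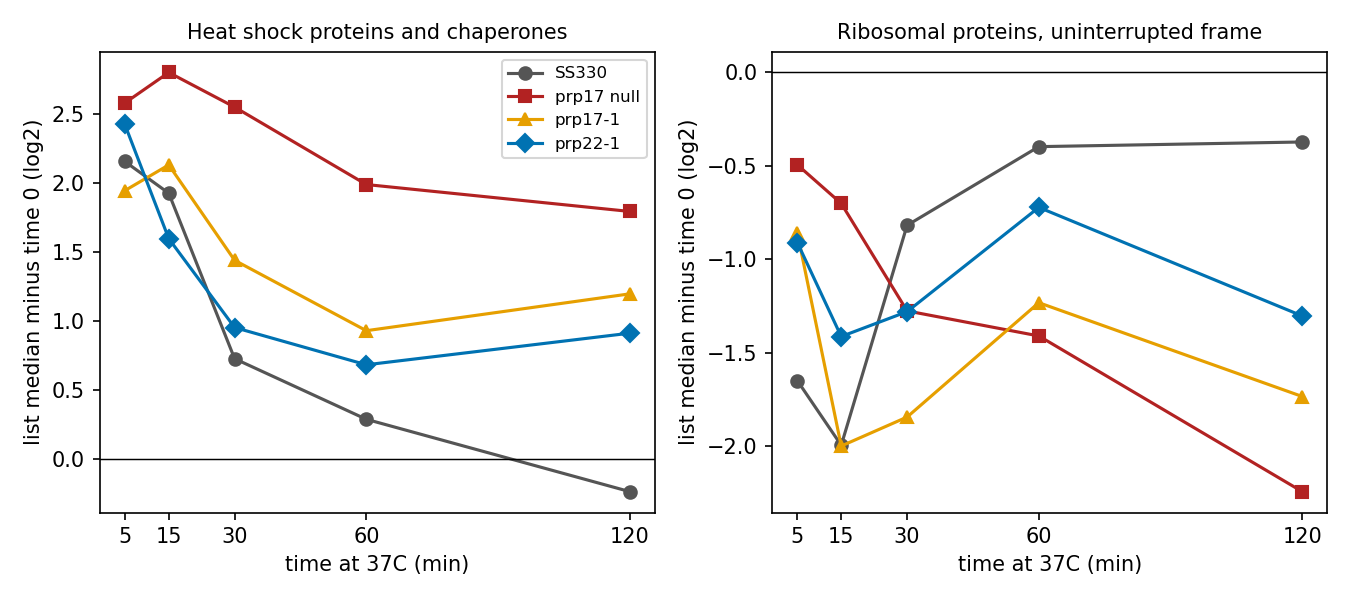
Median of 27 heat shock and chaperone genes (left) and of 73 ribosomal protein genes without an interrupted frame (right), as log2 minus the same strain's time 0 (vertical axes) against minutes at 37C (horizontal axes), with 1 line per strain, 1 array per point and no error bars. At 120 min the heat shock median was -0.24 in SS330, 1.79 in prp17 null, 1.19 in prp17-1 and 0.91 in prp22-1, and the ribosomal protein median was -0.37, -2.24, -1.73 and -1.30.

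At 37C the prp17 null strain had more mRNA than SS330 of heat-inducible chaperones and less of genes for ribosome production, mitochondrial ribosomes and glycolysis. With an estimated correlation none of these lists passed (adjusted p = 0.365 for heat shock and 0.693 for the others), and those of ribosomal proteins, mitochondrial ribosomes and glycolysis were already lower before the shift. Among genes with the same sign at all 5 times the largest rises were in HSP78, a mitochondrial disaggregase gene (3.38 ± 0.53, SE, adjusted p = 0.000393), SSA3 (3.19), SPI1 (2.88), BTN2, which acts in sorting of misfolded protein (2.62), SSA4, another Hsp70 gene (2.54), the reticulon gene RTN2 (2.49), HIS3 (2.37) and DAP1, a heme-binding protein gene (2.34). The largest falls among them were in PRE3, a proteasome core subunit gene (-2.61 ± 0.31, SE, adjusted p = 5.2e-05), SAR1, the GTPase of vesicle budding from the endoplasmic reticulum (-2.22), the transporter gene AQR1 (-1.91), ILV5 of branched-chain amino acid synthesis (-1.90), the nucleolar protein gene NSR1 (-1.71), SAM1 (-1.70), the cyclin gene CLB1 (-1.64) and the glycolytic gene TPI1 (-1.62). Of these, DAP1 was already higher at time 0 (1.31), AQR1 (-1.16) and CLB1 (-1.01) were already lower, and SPI1 was lower then (-1.20). PRE3 and SAR1 belong to the 86 interrupted-frame genes that do not encode ribosomal proteins, of which 42 were lower and 7 higher. Of the marker genes LYS2 was higher (0.90) and LEU2 lower (-0.60, and -1.19 at time 0), while URA3 (-0.20), TRP1 (0.05) and the receptor gene STE2 (0.40) did not pass.

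Of 27 heat shock and chaperone genes 19 were higher and 1, MGE1, was lower (20 and 1 adjusted over the list alone, median 1.28, adjusted p = 0.365 with an estimated correlation). Of 33 general stress genes 12 were higher and 1 lower (17 and 1 adjusted over the list alone), with the chaperone-like gene HSP31 at 2.04 and the glycogen phosphorylase gene GPH1 at 1.85. Of 64 ribosome biogenesis genes 32 were lower and 1, ERB1, was higher (36 and 1 adjusted over the list alone), with the rRNA methyltransferase gene EMG1 at -1.08. Of 20 RNA polymerase I and III genes 8 were lower (12 adjusted over the list alone), with RPA43 at -1.09 and RPC40 at -0.92. Of 23 glycolysis genes 15 were lower and 1, CDC19, was higher (16 and 1 adjusted over the list alone), with ADH1 at -1.40. At time 0 the median of these genes was already -0.72, with TPI1 at -1.64 and ADH1 at -1.91, and the median of the change from 23C to 37C against that of SS330 was 0.03. Of 59 mitochondrial ribosomal protein genes 27 were lower and 1, RSM18, was higher, the same counts adjusted over the list alone, with MRPS12 at -0.83 and MRPL23 at -0.68. Their median was already -0.22 at time 0, with MRPS12 at -0.65, and the median of their change from 23C to 37C against that of SS330 was -0.01. The adjusted p with an estimated correlation was 0.693 for each of these lists from general stress on.

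Of 10 histone genes 6 were lower (8 adjusted over the list alone), with HTB1 at -1.31 and HTB2 at -1.27. Of 21 M/G1 genes 9 were lower (10 lower and 1 higher adjusted over the list alone), with the cell separation genes SCW11 at -1.37 and EGT2 at -1.16. At time 0 the medians of the histone and M/G1 lists were -0.44 and -0.33, with EGT2 at -1.04. Of 20 G2/M genes 7 were lower and 1, YNL058C, was higher, the same counts adjusted over the list alone. In that list SUR7, at -0.72, turned to 0.05 under quantile normalization. Of 73 ribosomal protein genes without an interrupted frame 27 were lower (33 adjusted over the list alone), with RPL4A at -1.57 (-1.35 at time 0) and RPL22B at -0.79. This list's median against SS330 was -0.58 at time 0, above SS330 at 5 min (0.47) and 15 min (0.65), and below it at 30, 60 and 120 min (-1.09, -1.72 and -2.46). Of 53 with an interrupted frame 19 were lower (20 adjusted over the list alone), with RPS23B at -1.36, and 1, RPS0B, was higher (2.31, 1 adjusted over the list alone). Of the 32 ribosomal protein genes without a textbook intron 11 were lower (13 adjusted over the list alone). The adjusted p with an estimated correlation was 0.693 for all of these lists. Of 34 RNA export and decay genes 14 were lower and 2, NPL3 and MEX67, were higher (14 and 3 adjusted over the list alone), with LSM2 at -1.16 and LSM4 at -0.81, subunits of the Lsm ring that binds U6 RNA or the ends of decaying mRNA. Of 86 other genes with an interrupted frame 42 were lower and 7 higher (45 and 7 adjusted over the list alone, median -0.44). Both of these lists had an adjusted p of 0.365 with an estimated correlation.

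In all, 1865 probes differed between prp17 null and SS330 at 37C, 831 higher and 1034 lower. The balance depended on the scaling, with 920 higher and 870 lower without centring and 590 and 669 under quantile normalization. With only the arrays of the 2 strains the count was 771 and with only 5, 15 and 30 min it was 648. The 42 interrupted-frame genes became 21 and 19. The prp17 null arrays at 37C were wider in spread, with an SD over probes of 0.816 to 1.05 against 0.418 to 0.783 in SS330.

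The prp17-1 strain differed from SS330 at 37C in fewer genes. Of these, the 3 FIT genes of siderophore iron uptake were higher. Lower were 13 of 86 interrupted-frame genes that do not encode ribosomal proteins, and some genes of glycolysis and cell separation. Among genes with the same sign at all 5 times the largest rises were in FIT3, a cell wall protein gene of siderophore iron uptake (1.78 ± 0.13, SE, adjusted p = 6.45e-07, and 2.19 at time 0), SPI1 (1.69 ± 0.38, adjusted p = 0.0268) and YRO2 (1.43 ± 0.22, adjusted p = 0.00188, and -1.17 at time 0). FAT3, which acts in fatty acid uptake, was higher by 1.15, CIP1 by 1.14, FMP48 by 1.13, the Hsp90 cochaperone gene SBA1 by 1.11 and the glucose transporter gene HXT7 by 1.07. The largest falls among them were in PRE3 (-1.88 ± 0.31, SE, adjusted p = 0.00266), the decarboxylase gene FDC1 (-1.83 ± 0.10, adjusted p = 1.27e-08, and -1.66 at time 0), TPI1 (-1.57), SAR1 (-1.57) and LSM7 (-1.51), followed by EGT2 (-1.44), the serine and threonine deaminase gene CHA1 (-1.34) and YIP3 (-1.27). PRE3, SAR1 and YIP3 have an interrupted frame.

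Of 27 heat shock and chaperone genes SBA1 and HSP30 (1.03) were higher, which are 2, against 6 adjusted over the list alone (adjusted p = 0.492 with an estimated correlation). Of 21 iron regulon genes 3 were higher, FIT3, FIT2 (2.05) and FIT1 (1.30), and 1, ATX1, was lower (3 and 3 adjusted over the list alone, median -0.06, adjusted p = 0.661 with an estimated correlation). Of 23 glycolysis genes 4 were lower, PFK1 (-1.26), TPI1, PGI1 and PFK2, and 1, HXT7, was higher (5 and 2 adjusted over the list alone, adjusted p = 0.661 with an estimated correlation). Of 21 M/G1 genes 3 were lower, EGT2, DSE2 (-1.14) and CTS1, all of cell separation (8 adjusted over the list alone, adjusted p = 0.11 with an estimated correlation). EGT2 and DSE2 were already lower at time 0 (-1.06 and -1.02), as was CHA1 (-1.56). Of 12 mating and pheromone genes 2 were lower, the G protein gene STE4 (-0.70) and the kinase gene FUS3 (-0.54), against 7 adjusted over the list alone (adjusted p = 0.113 with an estimated correlation). The ATP synthase genes ATP3 (0.58) and ATP16 (0.49) were the 2 higher of 43 respiratory genes (2 adjusted over the list alone). IMP3 was the 1 lower of 64 ribosome biogenesis genes (-0.53, 8 adjusted over the list alone) and MRP35 the 1 lower of 59 mitochondrial ribosomal protein genes (-0.53, 1 adjusted over the list alone). ERG8 was the 1 lower of 19 ergosterol genes (-0.68, 4 adjusted over the list alone). The adjusted p with an estimated correlation was 0.661, 0.661, 0.687 and 0.551 for these lists in turn. Of 53 ribosomal protein genes with an interrupted frame and 73 without, limma called 0 and 0 (0 and 0 adjusted over the list alone), with medians of -0.52 and -0.63 (adjusted p = 0.661 with an estimated correlation for each). At 5 min both were above SS330 (0.49 and 0.65). At 15, 30, 60 and 120 min both were below it, at -0.19, -0.85, -0.80 and -1.38 with an interrupted frame and -0.18, -1.21, -0.88 and -1.53 without. Of 86 other genes with an interrupted frame 13 were lower and 1, UBC13, was higher (29 and 2 adjusted over the list alone, median -0.29, adjusted p = 0.11 with an estimated correlation). HIS3 was 0.61 higher (adjusted p = 0.0424), and URA3 did not pass (0.57, adjusted p = 0.0637), nor did LYS2 (-0.25), LEU2 (-0.25), TRP1 (0.03), STE2 (-0.22) or PRP22 (0.10). The HIS3 value was low in both strains, at -1.58 in prp17-1 and -2.22 in SS330 at time 0.

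In all, 165 probes differed, 53 higher and 112 lower, or 32.1% higher, and under quantile normalization 530 differed, 240 higher and 290 lower, or 45.3% higher. The count was 81 without the time points as a block, 301 with only the arrays of the 2 strains, 46 with only 5, 15 and 30 min and 325 with only 30, 60 and 120 min. It was 815 with array weights, tried after the data were seen, and 259 without the 4 arrays that held values for under 85% of the probes. It fell to 86, 68 and 81 without the SS330 array at 30, 60 or 120 min and to 75, 92, 101 and 74 without the prp17-1 array at 15, 30, 60 or 120 min. The count of 13 interrupted-frame genes fell to 8, 7 and 8 without the SS330 array at 30, 60 or 120 min and to 8 without the prp17-1 array at 15 or at 30 min.

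In prp22-1 at 37C, 28 of 86 genes that have an interrupted reading frame and do not encode ribosomal proteins were lower than in SS330, among them SAR1, PFY1 and TUB1, and the 3 FIT genes of siderophore iron uptake were higher, as they were before the shift. An interrupted frame here means that the length from start to stop codon is not a multiple of 3, as an intron inside the gene can cause. Among genes with the same sign at all 5 times the largest falls were in SAR1 (-1.71 ± 0.34, SE, adjusted p = 0.00801), the cytochrome oxidase subunit gene COX4 (-1.68), the cholinephosphotransferase gene CPT1 (-1.56 ± 0.16, SE, adjusted p = 6.18e-05), YOP1, which shapes the endoplasmic reticulum (-1.50), the profilin gene PFY1 (-1.47), TUB1 (-1.44), the ribosome-associated protein gene TMA20 (-1.43) and the mannose phosphate isomerase gene PMI40 (-1.42). Of these, SAR1, CPT1, YOP1, PFY1, TUB1 and TMA20 have an interrupted frame. The largest rises among them were in FIT3 (1.56 ± 0.13, SE, adjusted p = 9.28e-06, and 1.07 at time 0), the ribosome-associated chaperone gene ZUO1 (1.15, and 1.34 at time 0), the kinase gene YPK2 (1.06), the polyamine transporter gene TPO2 (1.02), PRM7 (1.00), the chromatin remodeller gene CHD1 (0.98), the bromodomain gene BDF2 (0.90) and the calmodulin-dependent kinase gene CMK2 (0.85).

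Of 86 interrupted-frame genes that do not encode ribosomal proteins, 28 were lower and 0 higher (48 lower and 3 higher adjusted over the list alone), with a median of -0.45. This list kept its call with an estimated correlation (adjusted p = 0.000318) and in fry over its 39 complete genes (adjusted p = 0.000488). In fry the list also passed in prp17 null (adjusted p = 0.00371) and in prp17-1 (adjusted p = 0.0094). There it did not pass with an estimated correlation, so passing fry does not set prp22-1 apart. Among the list's lower members in prp22-1 were the secretory pathway genes ERD2 (-1.29) and SEC17 (-1.13), the ubiquitin conjugation gene UBC4 (-1.15) and UBC9 (-1.20). These were picked after their values were seen. Interrupted frames, ribosomal ones included, made up 28 of the 86 lower named probes, or 32.6%, against 139 of 4871 named probes tested, or 2.9% (two-sided Fisher's exact test across genes, p = 3.02e-23). In prp17-1 they made up 13 of 99, or 13.1% (p = 3.59e-06 in the same exact test), and in prp17 null 61 of 944, or 6.5% (p = 2.08e-11 in the same exact test). Genes are not independent replicates in these tests. None of the 53 ribosomal protein genes with an interrupted frame passed in prp22-1, with limma counts of 0 higher and 0 lower (0 adjusted over the list alone), and their median was -0.39 (adjusted p = 0.793 with an estimated correlation). At 5 and 15 min it was above SS330 (0.57 and 0.61), and at 30, 60 and 120 min below it (-0.67, -0.87 and -1.38). The test of the mean over the 5 times therefore averaged opposite signs. The prp22-1 counts of interrupted-frame genes fell from 28 to 18 and 17 without the SS330 array at 30 or 60 min. They were 14 with only 5, 15 and 30 min and 45 with array weights, tried after the data were seen.

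**Figure D3:**
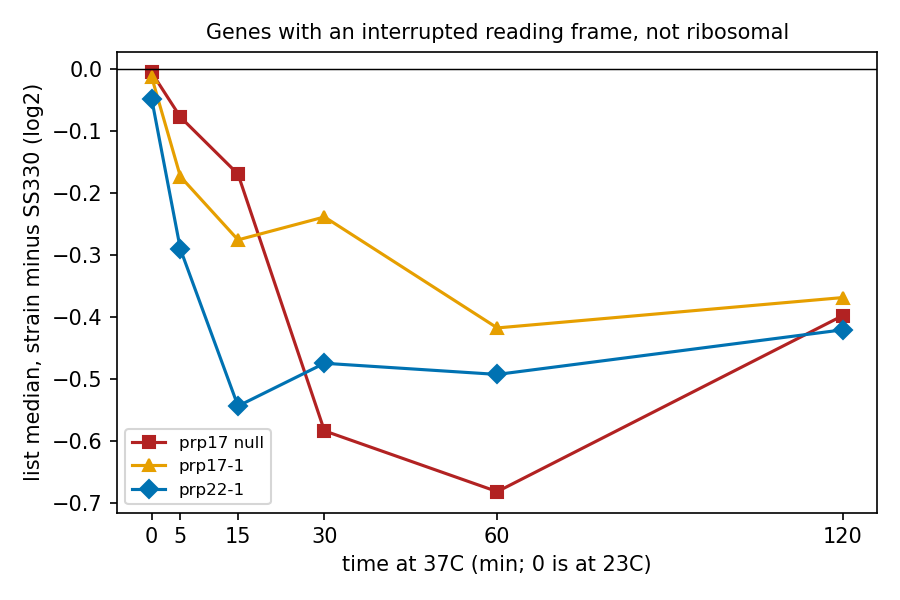
Median over 86 genes with an interrupted frame that do not encode ribosomal proteins, as the mutant strain minus SS330 on the log2 scale (vertical axis) against minutes at 37C (horizontal axis, 0 is at 23C), with 1 point per pair of arrays and no error bars. At time 0 the medians were -0.01 (prp17 null), -0.01 (prp17-1) and -0.05 (prp22-1), and at 15 min -0.17, -0.28 and -0.54.

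Of 12 tubulin and actin genes 6 were lower in prp22-1 (6 adjusted over the list alone, adjusted p = 0.0573 with an estimated correlation), and 4 of the 12 also have an interrupted frame. Besides PFY1 and TUB1 they included ACT1 (-1.12), SAC6 (-1.16) and COF1 (-1.46, with a value at 4 of the 5 times), while the second alpha-tubulin gene TUB3, which also has an interrupted frame, did not pass (-0.06, adjusted p = 0.911). The frame rule misses introns that keep the frame, such as that of ACT1. Members without an interrupted frame are therefore not shown to lack an intron. Of 11 auxotrophic marker genes 4 were lower (7 adjusted over the list alone, adjusted p = 3.56e-06 with an estimated correlation). Their median was -0.63 at 37C and already -0.37 at time 0, and their change from 23C to 37C did not pass (adjusted p = 0.984 with an estimated correlation). The genotypes of the strains at these genes are not known here, so a difference in strain background is not excluded. URA3 was at -1.09 and already lower at time 0, HIS4 at -0.83 (-1.25 at time 0), ADE1 at -0.64 and MET17 at -2.26 with 3 arrays at 37C. LYS2 did not pass (-0.88, adjusted p = 0.0545), nor did HIS3 (-0.01), LEU2 (-0.35), TRP1 (-0.04) or STE2 (0.36). Of 13 phosphate regulon genes 3 were lower, VTC3 (-1.27) and VTC4 (-0.87) of polyphosphate synthesis and SPL2 (-0.85), against 4 adjusted over the list alone (adjusted p = 1.32e-05 with an estimated correlation). Their median was already -0.20 at time 0, and their change from 23C to 37C did not pass (adjusted p = 0.276 with an estimated correlation). For the marker and phosphate lists the estimated correlation was 0, from 5 and 4 complete genes. For these lists it is therefore no stricter than the preset 0.01. BAR1, the protease gene of a-type cells that destroys alpha factor, was the 1 higher of the 12 mating genes (2.90 ± 0.28, SE, adjusted p = 0.000163, 3 arrays, 1 adjusted over the list alone) and was 2.59 higher at time 0. Of 21 iron regulon genes 3 were higher, FIT3, FIT2 (1.67, and 0.80 at time 0) and FIT1 (1.26, and 1.11 at time 0), the last 2 with a value at 4 of the 5 times, also 3 adjusted over the list alone. The list's median was -0.07 (adjusted p = 0.564 with an estimated correlation).

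Of 51 amino acid biosynthesis genes 5 were lower (11 adjusted over the list alone), ILV3 (-0.95), CPA1 (-0.86), LYS9, HIS4 and MET17, and of 43 respiratory genes 5 were lower (9 adjusted over the list alone), COX4, QCR10 (-0.92), ATP7, COX12 and NDE1. With an estimated correlation their adjusted p was 0.107 and 0.564. The respiratory genes were lower still at time 0 (median -0.45, against -0.20 at 37C), with COX4 at -1.28. Of 29 G1/S genes 3 were lower (4 adjusted over the list alone), the replication genes POL30 (-1.13) and RFA2 (-1.10) and the gene TOS4. UTP13 was the 1 lower of 64 ribosome biogenesis genes (-0.58, 1 adjusted over the list alone), and RPS29B (-1.35) and RPL32 were the 2 lower of 73 ribosomal protein genes without an interrupted frame (3 adjusted over the list alone). For these lists in turn the adjusted p was 0.564, 0.766 and 0.793 with an estimated correlation. No heat shock or chaperone gene of 27 passed, with limma counts of 0 and 0 adjusted over the list alone and a median of 0.31 (adjusted p = 0.707 with an estimated correlation).

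In all, 194 probes differed between prp22-1 and SS330 at 37C, 102 higher and 92 lower, and 422 under quantile normalization. Of the 102 higher probes only 50 were named, and 44 were unnamed probes after the last named one. Array weights, tried after the data were seen, gave 636, and only 5, 15 and 30 min gave 57. The count was 103 and 126 without the SS330 array at 60 or at 120 min.

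Whether a mutant's difference from SS330 was larger at 37C than at 23C was tested as an interaction, which rests on 1 array per strain at 23C. No gene passed in any strain with limma. The counts were 0 of 4886 probes for prp17 null, 0 of 5211 for prp17-1 and 0 of 5237 for prp22-1, with 375, 75 and 127 probes at an unadjusted p under 0.05. Under quantile normalization 267, 123 and 203 probes passed. The smallest p-values belonged to SRL2 in prp17 null (1.82 ± 0.32, SE, adjusted p = 0.15), to CIP1 in prp17-1 (1.94 ± 0.36, SE, adjusted p = 0.287) and to CIP1 in prp22-1 (1.54 ± 0.36, SE, adjusted p = 0.999). Next came NDC1 (-1.34), XKS1 (2.86) and PRM7 (2.22) in prp17 null, YRO2 (2.59), UBC4 (-1.57) and SNC1 (-1.26) in prp17-1, and ERD2 (-1.35), SLN1 (-1.14) and ATF2 (-1.25) in prp22-1, none of which passed. The interrupted-frame list had a median of -0.42 in prp22-1, -0.40 in prp17 null and -0.24 in prp17-1. No member passed over all genes in limma, against 0, 2 and 1 lower adjusted over the list alone, and the adjusted p was 0.108, 0.561 and 0.437 with an estimated correlation. In simulated data a change of 2 on the log2 scale was recovered for 70.2%, 71.4% and 68.8% of changed probes in these tests and a change of 1 for 17.7%, 15.4% and 15.4%.

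Between the alleles of PRP17, prp17-1 had more mRNA than prp17 null of the 3 FIT genes, of the glucose transporter genes HXT6 and HXT7 and of some histone genes, and less of some heat-inducible chaperones at 37C. FIT3 was 2.19 ± 0.13 higher (SE, adjusted p = 5.01e-08), the glucose transporter genes HXT7 1.87 and HXT6 1.64, the aldehyde dehydrogenase gene ALD6 1.74, CDC40 1.71 ± 0.16 (SE, adjusted p = 1.06e-05), the histone H4 genes HHF1 1.61 and HHF2 1.42, and the peptide transporter gene OPT1 1.36. HSP78 was lower (-2.16 ± 0.53, SE, adjusted p = 0.0163), as were DAP1 (-2.13), HSP31 (-2.01), the transcription factor gene SMP1 (-2.00), RTN2 (-1.96), SSA4 (-1.82), HIS3 (-1.76) and YNL134C (-1.67). At time 0 the differences were already 2.65 for FIT3, 2.97 for CDC40, 1.20 for ALD6, -1.20 for HSP31, -1.89 for HIS3 and -1.37 for YNL134C. Of the marker genes LYS2 was lower (-1.15, with a value at 4 of the 5 times) and URA3 higher (0.78), and PRP22 was lower (-0.66), while LEU2 (0.35), TRP1 (-0.02) and STE2 (-0.62) did not pass.

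Of 27 heat shock and chaperone genes 6 were lower (12 lower and 1 higher adjusted over the list alone). Of 20 cell wall integrity genes 7 were lower (8 lower and 1 higher adjusted over the list alone), with the kinase gene SLT2 of that pathway at -1.12 and the phosphatase gene PTP2 at -0.88. Of 10 histone genes 4 were higher, HHF1, HHF2, HTA2 and HTZ1 (9 adjusted over the list alone). The histone median against SS330 already differed at time 0, at -0.44 in prp17 null and 0.23 in prp17-1. Of 21 iron regulon genes 3 were higher, FIT1, FIT2 and FIT3, and 4 lower, FTH1, CCC2, HMX1 and FRE1 (3 and 7 adjusted over the list alone, median 0.03). Of 23 glycolysis and glucose transport genes 7 were higher and 3 lower, the lower ones being PFK1, PFK2 and PGI1 (7 and 4 adjusted over the list alone). Of 20 RNA polymerase I and III genes 4 were higher, RPA43 (0.70), RPC40 (0.64), RPA12 and RPC17 (5 adjusted over the list alone), and of 64 ribosome biogenesis genes 4 were higher, NSR1 (0.93), TIF6 (0.63), UTP5 and RCL1 (4 adjusted over the list alone). PRI1 (0.37) was among 5 higher of 29 G1/S genes (7 adjusted over the list alone), with RFA3, TOS4, PCL1 and CSI2, and of 59 mitochondrial ribosomal protein genes 4 were higher, MRPS12 (0.50), MRPL23, MRPL35 and RSM26, and 1, RSM18, was lower (4 and 1 adjusted over the list alone). Of 33 general stress genes 3 were lower, HSP31, SOD2 and GPH1, and 1, GPP2, was higher (4 and 1 adjusted over the list alone), and the list's median of -0.26 turned to 0.18 under quantile normalization. The adjusted p with an estimated correlation was 0.921 for each of these lists.

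In all, 706 probes differed between the alleles, 333 higher and 373 lower in prp17-1, against 156 under quantile normalization, 355 with only the arrays of the 2 strains, 70 with only 5, 15 and 30 min and 435 without the time points as a block. The count was 427 and 469 without the prp17 null array at 30 or 120 min, and 440, 433, 434 and 392 without the prp17-1 array at 5, 30, 60 or 120 min.

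The mutants shared some of these calls, though all were set against the same SS330 arrays. Between prp17 null and prp17-1, 39 probes were higher in both, 91 lower in both and 5 opposite, where independent lists would share 8 and 21.1. The covariance of their log2 differences was 0.116, against 0.0199 for simulated unchanged strains, and 0.0831 and 0.111 with the SS330 arrays split between the mutants. The correlation across probes was 0.690 against 0.490. Between prp17 null and prp22-1, 29 were higher in both, 62 lower in both and 10 opposite (15.4 and 17.3 shared for independent lists), with a covariance of 0.0792 against 0.0202, and 0.0403 and 0.0806 with the arrays split. Between prp17-1 and prp22-1, 12 were higher in both, 19 lower in both and 0 opposite (1.0 and 1.9 shared for independent lists), with a covariance of 0.0480 against 0.0199, and 0.0261 and 0.0388 with the arrays split. PRE3, for example, was at -2.61 in prp17 null and -1.88 in prp17-1, and SAR1 was lower in all 3 mutants. The correlation across probes in the last pairs was 0.455 and 0.463, no higher than the 0.494 of simulated unchanged strains for each. Probes are not independent replicates, and how much of the overlap comes from the shared SS330 arrays was not separated from the smaller number of arrays in the split fits.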

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

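Of the tests below, that of dim probes and both of the larger count in prp17 null were chosen after the result was seen. Single arrays stood far from the others of their strain in 5 genes, picked out by Dixon's test on the 5 differences from SS330 at 37C. STE4 in prp17-1 was -0.27 at 60 min and -0.93 to -0.74 at the other times. In prp22-1, CHD1 was 1.83 at 15 min (0.66 to 0.88 otherwise), CMK2 was 1.83 at 120 min (0.44 to 0.75), SAR1 was -0.93 at 5 min (-1.96 to -1.81) and VTC3 was -2.74 at 120 min (-0.97 to -0.83). Chance flags about 1 in 20 such groups, or 5.3 of the 107 tested, and 5 were found.

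For some genes the differences of 2 mutants from SS330 had opposite signs at all 5 times. FIT3 was -0.41 in prp17 null and 1.78 in prp17-1, and HXT7 was -0.80 and 1.07, differences that passed between the alleles (2.19, adjusted p = 5.01e-08, and 1.87, adjusted p = 0.000417). For the other pairs the difference was not tested. These are FIT3 (-0.41 in prp17 null, 1.56 in prp22-1), LSM4 (-0.81 in prp17 null and -0.23 in prp17-1, 0.16 in prp22-1), LYS2 (0.90 in prp17 null, -0.88 in prp22-1), PRM7 (-1.14 in prp17 null, 1.00 in prp22-1) and URA3 (0.57 in prp17-1, -1.09 in prp22-1). The differences of LSM4 in prp17-1 and prp22-1, LYS2 in prp22-1 and URA3 in prp17-1 did not pass.

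The unnamed probes with the highest identifiers enter the counts of changed probes but stand for no named gene. They gave a signal in prp22-1: 44 of 163 were higher than in SS330 at 37C and 1 lower, or 27.0% higher against 1.09% of the other probes. As a list the block did not pass with an estimated correlation (adjusted p = 0.556) or in fry (adjusted p = 0.904). The block's median was 0.17 in prp22-1 and also 0.17 in prp17-1, where 7 were higher and 1 lower, and in prp17 null 20 were higher and 16 lower. The 44 probes had their highest median against SS330 in prp22-1 at 15 min (1.499), on the array with values for 77.3% of the probes. At 5, 30, 60 and 120 min the median was 0.935, 0.734, 0.99 and 0.844, so the rise does not rest on that array alone. It was 0.16 at time 0. The probes were picked by their mean at 37C, so a higher median there is partly built in. Of the called probes 97.8% were higher, which restates the pattern, so noise of dim probes stays open. A shift of the whole block would leave few probes below 0, yet 39.3% were. Whether they hold intron sequences cannot be told, since 0 could be matched to an intron.

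Genes with an interrupted frame outside the ribosome were lower in prp22-1, with a median of -0.45. Of 10000 random lists matched for gene length the lowest median was -0.14, and matched for the response of SS330 to heat it was -0.14 against -0.46 for the 85 list members with such a match. Neither length nor the response to heat seen in SS330 accounts for a fall of that size. A stronger or longer response in prp22-1 itself was not matched, so it stays open. Random lists also lack the correlation between members of this list, estimated at 0.125. Loss of splicing is the biological explanation on offer, and without probes known to lie in introns it could not be tested apart from lower transcription.

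The prp17 null strain had more changed genes than prp17-1. Without the 4 arrays with few values the count of the null was 6.10 times that of prp17-1, and under quantile normalization, which removes a wider spread of values, it was 2.38 times. Each narrowed the ratio of the main counts (1865 against 165) and neither removed it. A difference between the cultures cannot be told from one between the alleles.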

How the results depend on the processing

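Of 4870 repeats for named genes, 4394 kept direction and side of the threshold, 443 no longer passed, 30 newly passed and 3 reversed, all under quantile normalization: PRE7 in the shift (-0.17), SUR7 in prp17 null (0.048) and HIS3 in prp22-1 (0.59). Unless said otherwise, the cause of a change below was not tested. Array weights and leaving out arrays with few values were chosen after seeing the data.

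Under quantile normalization the counts were 530 (prp17-1), 422 (prp22-1), 156 (prp17-1 against null) and 267, 123 and 203 (interactions of null, prp17-1, prp22-1), with 21 interrupted-frame genes lower in prp17-1. Array weights gave 815 and 636 for prp17-1 and prp22-1, with 33 and 45 interrupted-frame genes. Without the arrays with few values prp17-1 had 259.

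Fewer probes tested, those complete on all arrays, gave 954 (shift), 878 (null), 105 (prp17-1), 79 (prp22-1) and 321 (between alleles), with 19, 7 and 15 interrupted-frame genes. The stricter adjusted p under 0.01 gave 993, 952, 48, 84 and 183, with 6 and 15 interrupted-frame genes in prp17-1 and prp22-1. With no block for the time point or strain the shift had 1063, prp17-1 81 and the alleles 435.

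With only the arrays of the strains compared, the counts were 771 (null), 301 (prp17-1) and 355 (alleles), with 21 interrupted-frame genes in each of null and prp17-1. Fewer arrays, those of 5, 15 and 30 min, gave 648, 46, 57 and 70 for null, prp17-1, prp22-1 and the alleles, 1 for the null interaction, and 19, 5 and 14 interrupted-frame genes. Those of 30, 60 and 120 min gave 325 in prp17-1, with 20 interrupted-frame genes, and 18 for the null interaction.

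Leaving out each array in turn gave 1267 to 2052 (null), 68 to 177 (prp17-1), 103 to 220 (prp22-1), 392 to 928 (alleles) and 0 to 0 (interactions), with 32 to 42, 7 to 17 and 17 to 30 interrupted-frame genes. The shift, leaving out a strain or a time, gave 906 (without prp17-1) to 1753. The other settings, no centring, centring without ribosomal protein genes, a filter at 12 arrays, and trend and robust settings, left every count within 1.5 times. The planned comparison of introns with their exons was not run, as no intron annotation was given. Signal over background is not in the files, so what it limits cannot be given.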

Other observations

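The tests of late against early times, and of the heat shock list against matched lists, were chosen after the result was seen. In prp17 null the response to heat lasted longer than in SS330, while fewer genes passed in prp17-1 and no heat shock gene did in prp22-1. At 60 min, relative to its time 0, the disaggregase gene HSP104 was at 0.14 in SS330, 3.47 in prp17 null, 1.78 in prp17-1 and 1.52 in prp22-1, and SSA3 at 0.58, 5.49, 3.54 and 0.57. As the late times (60 and 120 min) minus the early times (5 and 15 min), set against the same in SS330, 624 probes differed in prp17 null, 33 in prp17-1 and 78 in prp22-1. Of 27 heat shock genes 11 were higher in prp17 null, among them SSA3 (3.80 ± 0.47, SE, adjusted p = 0.00102), SSA4 (3.21), HSP104 (2.59) and HSP82 (1.89). In prp17-1 only SSA4 passed (2.33, adjusted p = 0.0474), with SSA3 at 2.31 (adjusted p = 0.0541) and HSP104 at 2.15 (adjusted p = 0.0949). In prp22-1 limma called 0 of the 27. There BTN2 was at 1.96, HSP42 at 1.55, HSP104 at 1.39, SSA4 at 1.05, HSP82 at 0.93, SSE1 at 0.54, STI1 at 0.46, SSA3 at -0.42 and HSP78 at -0.89, none of which passed. The median of the list was 1.24, 0.79 and 0.54 in prp17 null, prp17-1 and prp22-1. Random lists matched for the early response had a median of 0.77, 0.47 and 0.34 and reached 1.30, 0.98 and 0.80, and 0.06%, 0.58% and 0.99% of them were as high, so much of the difference belongs to all genes with that early response. The proteasome list was also higher late minus early, with medians of 0.90, 1.16 and 0.54. Of its genes 11 of 33 were higher and 1 lower in prp17 null, 5 of 32 higher in prp17-1 and 0 of 33 in prp22-1.

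Ribosomal protein mRNAs came back towards their starting level in SS330 and went on falling in prp17 null. The median of those without an interrupted frame, relative to time 0, was -1.65, -2.00, -0.82, -0.40 and -0.37 at 5, 15, 30, 60 and 120 min in SS330 and -0.49, -0.70, -1.28, -1.41 and -2.24 in prp17 null, so part of the difference between late and early times comes from a smaller early fall. Of those with an interrupted frame and without, 46 of 52 and 65 of 72 were lower late minus early in prp17 null, 7 of 53 and 4 of 72 in prp17-1, and 22 of 53 and 20 of 73 in prp22-1. Of those known from textbooks to lack an intron, 30 of 32 were lower in prp17 null, 0 of 31 in prp17-1 and 3 of 32 in prp22-1, with medians of -2.78, -1.54 and -1.14. The medians of those with an interrupted frame were -2.31, -1.32 and -1.62. In prp17 null the lower values at late times therefore include genes without an intron, and in prp17-1 and prp22-1 the medians of such genes were below 0 as well, about as far as those with an interrupted frame in prp17-1 and less far in prp22-1. In simulated data a change of 1 on the log2 scale was recovered for 6.0%, 1.5% and 4.5% of probes in these tests, so few calls do not show that few genes changed.

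Arrays were exchanged between the compared groups to set the counts beside those of other groupings. In each comparison 1 of 100 groupings, the real one, had as many changed probes. The highest other count was 353 for the shift (1690 real), 15 for prp17-1 (165), 4 for prp22-1 (194) and 164 between the alleles (706). For prp17 null it was 1416 (1865), from the grouping that exchanged SS330 at 5 min with the null at 15 min, and with 2 arrays exchanged per strain it was 323. The arrays of a strain are times of 1 course, and many exchanges between strains mixed different times, which breaks the time block. A difference between cultures or arrays would also put the real grouping first. These counts therefore do not show that the strain is the cause.

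Arrays of the same time correlated after each strain's mean was removed, with a mean r of 0.409 for SS330 and prp17-1, 0.428 for SS330 and prp22-1 and 0.032 for SS330 and prp17 null, so the time point as a block takes up little of the spread in the comparison of prp17 null.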
